A study of Homo sapiens with 6 samples.

How the data were processed

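Small RNA was sequenced from extracellular vesicles of human pulmonary arterial endothelial cells kept for 24 h at 0.5% oxygen after transfection with a control siRNA (siControl, 3 libraries) or an siRNA against BMPR2 (siBMPR2, 3 libraries). Per the labels' protocols, the medium held 5% serum depleted of exosomes, vesicles were collected by differential centrifugation, RNA came from a kit for small RNA, and libraries were made with a kit that ligates adapters to small RNA. The labels call the libraries of a group biological replicates and do not say whether they came from separate cultures or donors, so the p-values measure the spread between these libraries.

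The authors deposited 1 table per library, and all tables listed the same 175946 annotated intervals. Per the submitters' processing notes, Trim Galore 0.4.0 and Bowtie2 2.2.4 were used and the genome build was GRCh38. The tool that counted reads is not given in the sources used here. The deposited columns held whole-number read counts per interval with no normalization, the number of bases covered, the interval length, and the covered fraction of the interval, all as read from the deposited values. The deposited fraction equalled covered bases over length. The deposited coverage, as the number of covered bases, was used for the lncRNA intervals.

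Several properties of the deposited counts shaped the analysis. Removing 25 bases at each end made 21570 intervals equal to a gene of GENCODE release 29, against 0 with no bases removed, so intervals were padded by 25 bases, and positions are given here without the padding. A read was counted in every interval it overlapped. For 147 small RNA intervals with at least 1000 reads that lay inside a lncRNA interval of the opposite strand, the long interval held at least as many reads in every library for all 147, so strand did not separate the counts. Reads of the 5' and 3' arm of a miRNA hairpin, and reads shared by near-identical gene copies, therefore could not be separated, and values of such copies are uncertain. Intervals of lncRNA made up 88.2% of rows and 87.1% of the summed counts, while those kept without overlap (below) held 2.49% to 7.30% of a library's reads.

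A set of features chosen to limit shared reads was built for this reason. Each of 1916 miRNA loci was represented by its row with the highest total, since adding the rows of a locus would have counted the same reads more than once. The plan fixed in advance was to sum rows per gene, and it was changed on this point. The other small RNAs were kept where no interval without its padding overlapped one already kept. Counts covered the padding, so close neighbours could still share reads. The 4991 lncRNA intervals that overlapped a small RNA, padding included, were left out. The resulting 33413 features held 6466416 to 13236204 reads per library. The 1916 miRNA loci held 730890 to 2649607 reads per library. Of these loci, 21 shared bases with other small RNAs. They were left out of the set but not removed before the miRNA fit. The set held no reads of mitochondrial RNA, whose intervals were at 0 in all 6 libraries. The tables held 0 rows named BMPR2 and no intervals for the fixed mRNA lists that could be tested, so the silencing and these lists were not analysed here.

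Groups and replicate numbers came from the labels. No 2 libraries held identical values, and replicate libraries of a group differed by far more than counting noise, with a chi-square per degree of freedom of 175 to 504. Deviations from the group means correlated between libraries of the same number (r = 0.584, 0.781 and 0.738 across miRNA loci) and less between libraries of different numbers (r from -0.583 to 0.058). Deviations cancel out within a group, so high values for like numbers in part force low ones for unlike numbers. With so few libraries, a match of numbers can also arise by chance. The numbers were taken to pair the libraries on this limited check of the data, since the labels do not say what a number marks.

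Changes were tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr with a count minimum of 10, group as the only term), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The miRNA loci were fitted alone, with library sizes over the reads of tested miRNA loci, and all features were fitted together, with library sizes over the reads of tested features. Fold changes are log2 values of siBMPR2 over siControl with their standard errors. In edgeR the standard error was taken as the absolute fold change over the square root of the test's F value. It therefore restates the p-value. CPM is counts per 1000000 of a library's size in the same fit after multiplication by its TMM factor, which was 0.817 to 1.197 in the miRNA fit, so a CPM differs from the plain share of miRNA reads. The filter of 10 CPM used library sizes before that factor. Lists of miRNAs written before the data were examined were tested with camera in limma 3.58.1 at an inter-gene correlation of 0.01 on voom values, where at least 3 members were tested. Adjusted p-values of lists were taken over the 18 miRNA lists, and separately over 6 lists of other RNA classes in the fit of all features. Shares of reads by RNA class were compared by a two-sided exact permutation test, whose smallest p for 3 against 3 is 0.1. The erythroid list had 2 tested members and was not tested.

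Named miRNAs and genes were chosen by a rule fixed before the data were examined: up to 10 miRNAs per direction past the threshold, or the 5 of smallest p in a direction where fewer than 5 passed; the 10 most abundant miRNAs; the 4 most abundant members of each list; and up to 5 other features per direction past the threshold. Names outside the rule are said to be so where they appear.

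Alternatives were DESeq2 size factors, library totals, no low-count filter, a filter of 10 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a robust fit, library sizes over all features, gene copies summed, the replicate number as a block, and each library left out. Fits without a library had no block and kept its partner of the same number, which broke that pair. Alternatives chosen after the data were seen left out loci that shared bases with other small RNAs or had flat raw counts, corrected for GC content (302 of 309 tested loci had a value, from the reference genome), or left the called lncRNA intervals out of the class shares. Flat loci were those with a mean count of at least 50 and a highest count of at most 1.5 times the lowest. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

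The procedures were tested on simulated counts with 200 changed features. For miRNAs, the changed loci were drawn among 970 detected loci, and 66 of them passed the filter. Of these, 0% were called at 2-fold, 50.0% at 4-fold and 92.6% at 8-fold, with 0 false calls; with the block these shares were 52.6%, 100% and 100%, with 2 false calls. For all features, the changed ones were drawn among the 2015 tested features, and 179 passed the filter again. Of these, 0% were called at 2-fold, 1.9% at 4-fold and 67.8% at 8-fold, with 0 false calls; with the block these shares were 14.7%, 92.3% and 100%, with 3 false calls. A simulated list raised by 2-fold was called by camera, and 0 of 10 random lists were. Each locus was simulated independently, so this test could not show false calls from correlation between members of a list.

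At this depth the widest 95% Wilson interval of a class share in a library reached 0.0361 percentage points to either side. Such intervals cover counting error only, since the reads carried no molecular identifiers.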

Results

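Extracellular vesicles are membrane-bound particles that carry RNA out of cells. Those analysed here came from hypoxic pulmonary arterial endothelial cells, the lining of the vessel that leads to the lung, after silencing of BMPR2 or a control transfection. BMPR2 is a receptor for bone morphogenetic proteins, and its loss-of-function variants underlie heritable pulmonary arterial hypertension. The comparison asked which small RNAs of hypoxic vesicles differ when this receptor is silenced. There were 3 libraries per group, with 7478688, 11270598 and 7040072 reads in siControl replicates 1 to 3 and 6466416, 13236204 and 6711529 in siBMPR2 replicates 1 to 3. The tables held 0 rows named BMPR2, so the level of the silenced mRNA was not analysed here.

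The vesicles of both groups held mostly fragments of tRNA, Y RNA, snoRNA and rRNA beside miRNA. Y RNAs, small RNAs bound by the Ro60 protein, gave 21.7% ± 4.5 of reads in siControl and 30.2% ± 4.6 in siBMPR2 (SD, n = 3 each). Fragments of tRNA gave 25.2% ± 10.4 and 23.5% ± 7.6, and miRNAs gave 16.9% ± 5.7 and 13.9% ± 4.1. The share of snoRNAs, which guide the modification of other RNAs, was 16.0% ± 6.0 and 18.8% ± 7.8, higher with BMPR2 silenced in 3 of 3 pairs. The share of lncRNA intervals was 5.58% ± 1.92 and 3.02% ± 0.81, lower in 3 of 3 pairs. The single lncRNA intervals that passed the test carried much of that difference of -2.56 points: without these 23, a setting chosen after the data were seen, it was -1.25 points (exact permutation p = 0.1, the smallest possible), and without siControl 1 it was -1.69. LINC02331, a called interval named after its values were seen, gave 3.87% of all reads in siControl 1. Reads of rRNA gave 14.3% ± 12.1 and 10.2% ± 1.9, and the siControl spread came from replicate 3 at 28.3%.

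No share of the 10 RNA classes passed the test. The two-sided exact permutation p was 0.2 for Y RNA and for lncRNA, 0.5 for miRNA, 0.7 for snoRNA, 0.6 for tRNA and 0.9 for rRNA, where the smallest that 3 against 3 libraries allow is 0.1. Adjusted over the 10 classes, p was 0.75 or higher. Groups overlapped in all 10 classes, where chance alone parts 10% of them. The 3 pairs went one way in 3 of the 10 classes, and so few pairs often agree by chance. Of the 4 smallest classes, RNase P and MRP RNA gave 0.0588% and 0.0883%, higher in 3 of 3 pairs (exact permutation p = 0.3), with snRNA at 0.312% and 0.268%, 7SL RNA at 0.0305% and 0.0281%, and vault RNA at 0.0203% and 0.0254%.

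**Figure D1:**
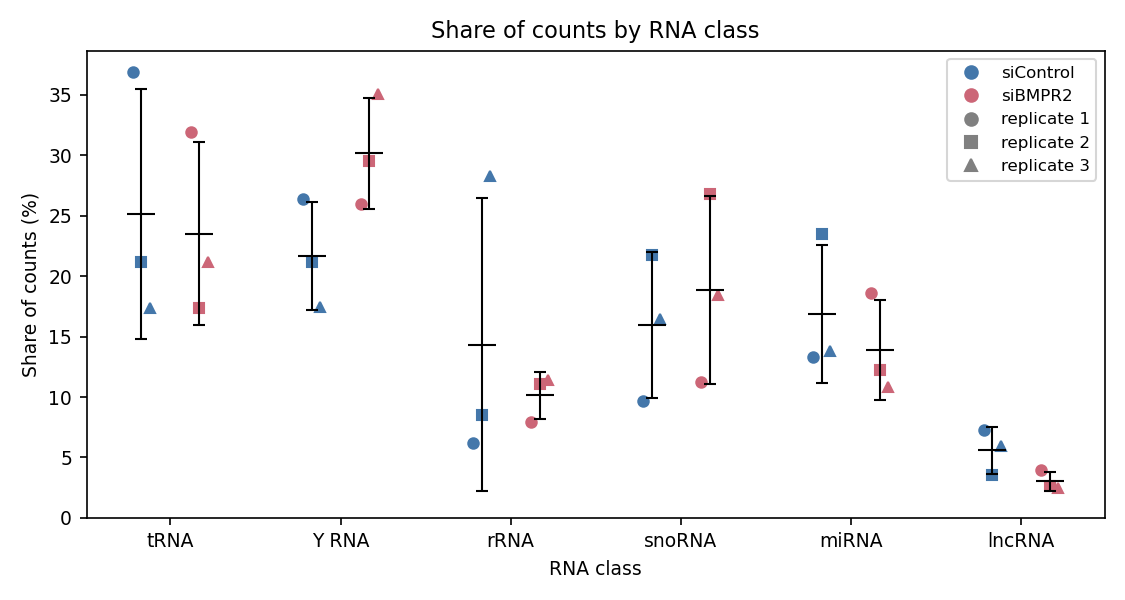
Share of reads (%, vertical axis) in the 6 RNA classes that reach 1% in a library (horizontal axis). Points are libraries, coloured by group and shaped by replicate number, and bars give the mean and SD of 3 libraries. The Y RNA shares of siBMPR2 lay between 25.95% and 35.1% and those of siControl between 17.4% and 26.4%, so the groups overlapped.

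The same miRNAs led the vesicles of both groups. MIR21, at 258800 ± 111600 CPM in siControl and 227300 ± 75310 in siBMPR2 (SD, n = 3 each), and MIR126, an endothelial miRNA that supports vessel integrity, at 192400 ± 10940 and 160500 ± 23000, were the most abundant. MIRLET7I (103300 ± 10420 and 111700 ± 14710), MIR99A (40850 ± 13580 and 59670 ± 14480) and MIR100 (34540 ± 26550 and 41780 ± 35450) followed. The other 5 of the 10 most abundant were MIRLET7G, MIR30A, MIR26A2, MIR26A1 and MIR151A, with mean levels of 30490 to 16670 CPM over all libraries. Their log2 fold changes lay between -0.30 for MIR30A and 0.55 for MIR99A, and none passed the test. MIR26A1 and MIR26A2 give the same mature miRNA and cannot be separated.

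No miRNA passed the test between siBMPR2 and siControl vesicles. Of 309 tested loci, edgeR called 0, with 13 at an unadjusted p under 0.05, of which 7 were higher and 6 lower. DESeq2 called 0 with 12 at that level, limma-voom 0 with 14, and the fit with the replicate number as a block 0 with 56, where the smallest adjusted p was 0.0752. Scaling by reads of all features moved the median log2 fold change of the loci from 0.055 to -0.087 and the split at that level to 1 higher and 10 lower; with DESeq2 size factors it was 4 and 7.

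The loci with the smallest p had values in the same direction in 3 of 3 pairs. They were chosen by p from the same libraries, so this agreement follows in large part from the choice. The miR-320 family gave 3 of the 5 on the higher side: MIR320A at 3235 ± 319 CPM in siControl and 5607 ± 1247 in siBMPR2 (log2 fold change 0.79 ± 0.29 SE), MIR320B1 at 0.87 ± 0.33 and MIR320B2 at 0.94 ± 0.36. The other two were MIR935 (1.25 ± 0.42) and MIR3615 (1.30 ± 0.55, and 2.17 without siControl 1). MIR320B1 and MIR320B2 are near-identical copies that cannot be separated, so they do not count as separate members of their family. On the lower side stood MIR103A1, MIR103A2 and MIR107, a seed family of miRNAs known to lower DICER1, at -0.96 ± 0.36, -0.94 ± 0.36 and -0.90 ± 0.37. MIR103A1 and MIR103A2 share their mature miRNA and cannot be separated; MIR103A1 was at 2288 ± 839 CPM in siControl and 1180 ± 131 in siBMPR2. MIR542 (-1.20 ± 0.43) and MIR185 (-0.98 ± 0.40) completed that side. The adjusted p of all 10 was 0.968 in edgeR with group as the only term. In edgeR with the replicate number as a block it was 0.0752 to 0.115.

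**Figure D2:**
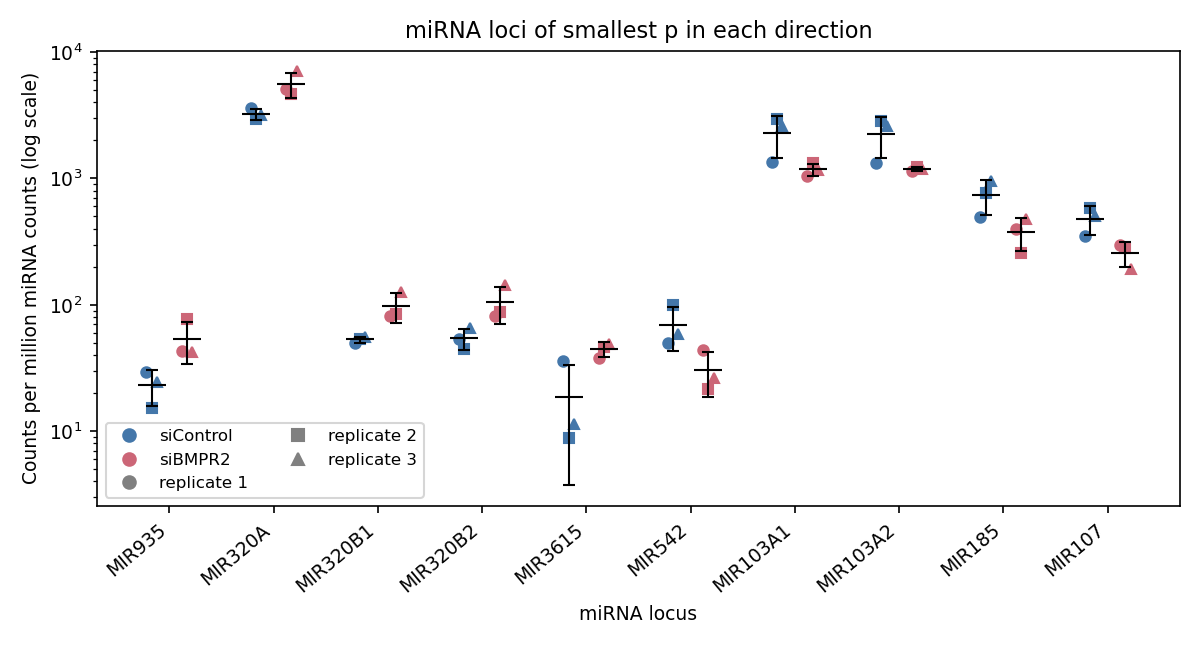
Level of the 10 miRNA loci of smallest p (horizontal axis), in CPM on a log scale (vertical axis). Points are libraries, coloured by group and shaped by replicate number, and bars give the mean and SD of 3 libraries. MIR320A lay at 3235 ± 319 in siControl and 5607 ± 1247 in siBMPR2, and none of the 10 passed the test.

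Of the fixed lists, 4 ranked lower in siBMPR2 vesicles than the other miRNA loci did, among them the miRNAs linked to vessel growth and to low oxygen. These calls were lost with an estimated correlation, with adjusted p = 0.851 for the hypoxia list and adjusted p = 0.644 for each of the other 3. The angiogenesis list had 22 of 31 tested members lower and 9 higher, with a median log2 fold change of -0.26 (camera adjusted p = 0.0174). In the hypoxia list, 18 of 23 were lower and 5 higher, at a median of -0.19 (adjusted p = 0.0275). All 4 members of the miR-29 family, which targets collagen mRNAs, had lower values, at a median of -0.66 (adjusted p = 0.0275). So were all 6 loci of the miR-23, miR-27 and miR-24 clusters, at a median of -0.38 (adjusted p = 0.0426), and these 6 are members of the angiogenesis list too. Abundant members included MIR126 (-0.26 ± 0.21), MIR27B (-0.47 ± 0.35), MIR24-2 (-0.45 ± 0.28) and MIR27A (-0.02 ± 0.46). In the miR-29 family, MIR29B2 was at -0.72 ± 0.38, MIR29B1 at -0.72 ± 0.41 and MIR29C at -0.61 ± 0.34, while MIR29A, by far its most abundant member at 9073 CPM, was at -0.04 ± 0.37. MIR29B1 and MIR29B2 are near-identical copies that cannot be separated, and so are MIR24-1 and MIR24-2. Lists were tested by locus, so such copies counted as separate members.

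Fry, which tests whether a list's members move one way without comparing them with other loci, called none of the 4 (adjusted p = 0.766 for angiogenesis, 0.962 for hypoxia and 0.765 for each of the other two). No member of any of the 18 lists passed the test over all loci, and with all 6 libraries and no block 0 passed when adjusted over the list alone; without siControl 1, MIR103A1 and MIR103A2 of the hypoxia list and MIR128-1 and MIR128-2 of the neural one did. The fits without a library, here and below, kept its partner of the same number and so broke a pair. Leaving out siControl 2 ended all 4 calls (adjusted p from 0.242 to 0.725) and moved the medians to -0.092 for angiogenesis, 0.04 for hypoxia (12 higher, 11 lower), -0.40 for miR-29 and -0.13 for the clusters (1 of 6 higher), with MIR27B at -0.065. Leaving out siBMPR2 3 ended all 4 (0.0601 to 0.188), with a hypoxia median of -0.049; this median was -0.40 without siControl 3, -0.34 without siBMPR2 1 and -0.12 with library totals. Without siControl 1 the miR-29 (0.213) and miR-23, miR-27 and miR-24 (0.103) calls ended, without siBMPR2 1 the hypoxia (0.0879) and the cluster (0.0775) calls, and without siBMPR2 2 the cluster call (0.0679).

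With the replicate number as a block, 11 members passed when adjusted over the list alone, each in the same direction in 3 of 3 pairs, and 0 over all loci. In the hypoxia list these were MIR103A1 (-0.89 ± 0.25), MIR103A2 (-0.86 ± 0.25), MIR107 (-0.89 ± 0.30), MIR503 (-0.88 ± 0.31) and MIR93 (-0.68 ± 0.24), with list-adjusted edgeR p from 0.0256 to 0.0488. In the miR-29 family they were MIR29B2 (-0.75 ± 0.29) and MIR29B1 (-0.74 ± 0.30), both at 0.0401. The others were MIR99A (0.57 ± 0.16, list-adjusted p = 0.0354) among endothelial miRNAs, MIR128-1 and MIR128-2 (0.65 ± 0.27 and 0.70 ± 0.27, 0.0358) among neural ones, and MIR150 (-0.90 ± 0.29, 0.0264) among those of leukocytes and platelets. MIR103A1 and MIR103A2, MIR29B1 and MIR29B2, and MIR128-1 and MIR128-2 are pairs of near-identical copies. Such copies cannot be separated, so the 11 members are fewer distinct miRNAs. All 11 were chosen by a test on the same pairs, so their shared direction is no separate support. MIR503 and MIR150 are named after their values were seen. With GC correction beside the block, the calls of MIR107, MIR503, MIR93, MIR99A, MIR128-1 and MIR128-2 ended, while MIR103A1, MIR103A2, MIR29B1, MIR29B2 and MIR150 passed and MIR29C was added. The neural median was 0.652 with the block alone and 0.645 with both, and the hypoxia median -0.17 and -0.228. The endothelial median was -0.102 with the block alone and -0.079 with both. These medians cover whole lists, so they do not show whether the values of the members that lost their call shrank.

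The remaining 14 miRNA lists did not pass. The list linked to pulmonary arterial hypertension had 15 of 21 members lower at a median of -0.28 (adjusted p = 0.0544), and passed with library totals (0.0388), without flat loci (0.0281), after GC correction (0.022), with the block and GC correction together (0.0263) and without siControl 3 (0.048). With an estimated correlation these calls were lost, at adjusted p = 0.605, 0.617, 0.59, 0.92 and 0.786. Without siControl 2 its median was -0.10 (adjusted p = 0.429), and without siBMPR2 2 it was -0.175 (0.261). The miR-17-92 paralogs had a median of -0.21 and the miRNAs known to target BMPR2 one of -0.19, with MIR93 at -0.81 ± 0.52 and MIR25 at 0.35 ± 0.30. The first median was -0.12 without siControl 1 or siControl 2, and the second was -0.001 without siBMPR2 3. The let-7 family was at -0.13, the miR-30 family at -0.053, and the miRNAs of inflammation and senescence at -0.064, with MIR146A at -0.09 ± 0.58 and MIR221 at 0.32 ± 0.36. The BMP and TGF-beta list had 15 members on each side (median 0.036). The imprinted DLK1-DIO3 cluster was at -0.059 with all libraries, at -0.48 without siControl 2 (adjusted p = 8.93e-09), at 0.53 without siControl 3 (0.00652) and at 0.40 without siBMPR2 2 (0.000109). With an estimated correlation these 3 calls were lost, at adjusted p = 0.803, 0.786 and 0.692.

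Markers of cell types did not pass either. Endothelial miRNAs had a median of -0.059 over 18 members, miRNAs of muscle and fibroblasts one of 0.12, of leukocytes and platelets 0.27, of epithelium 0.24, of liver and serum 0.47 and of neural cells 0.55. With 1 library left out, the lowest medians of the last 3 were 0.048 (without siControl 2), 0.11 (without siBMPR2 1) and 0.28 (without siBMPR2 2). MIR155, a leukocyte miRNA, was at 0.36 ± 0.32, MIR122, the main liver miRNA, at 1.05 ± 0.88 with a mean of 34.3 CPM, and MIR128-1 at 0.55 ± 0.39; their lowest values were 0.094 (without siBMPR2 3), 0.49 (without siBMPR2 1) and 0.30 (without siControl 3). Median, mean and test differed in sign for the lists of BMP and TGF-beta (mean -0.052), endothelium (mean 0.032), muscle and fibroblasts (mean -0.034), leukocytes and platelets (tested as lower), and the DLK1-DIO3 cluster (tested as higher). Some members had near-equal raw counts in every library, whatever its depth: 6 of 30 in the BMP and TGF-beta list, 4 of 21 in the list of miRNAs that target BMPR2, 2 of 21 in the pulmonary hypertension list, 4 of 12 in muscle and fibroblasts, 1 of 14 in the miR-17-92 paralogs and 1 of 5 in leukocytes and platelets.

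**Figure D3:**
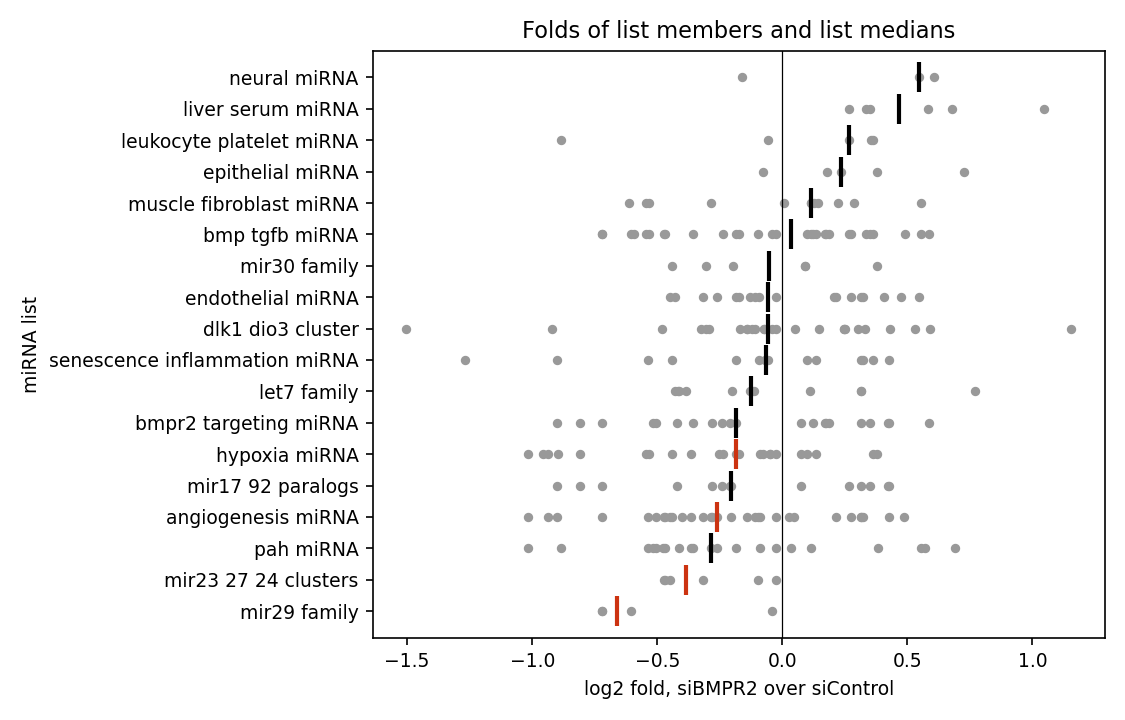
Log2 fold change of siBMPR2 over siControl (horizontal axis) for the tested members of each of 18 miRNA lists (vertical axis). Grey points are members, and vertical ticks are list medians, in red where the camera adjusted p was under 0.05. The 4 red medians lay between -0.66 and -0.19.

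Among the other small RNAs, C/D box snoRNAs, which guide ribose methylation, ranked higher as a list in siBMPR2 vesicles than the other features: 149 of 197 were higher and 48 lower, at a median log2 fold change of 0.22 (camera adjusted p = 0.000449, and adjusted p = 0.837 with an estimated correlation). Spliceosomal U RNAs passed too (adjusted p = 0.0334, and adjusted p = 0.837 with an estimated correlation), with 23 of 41 higher at a median of 0.037, which was -0.031 with library totals. H/ACA box snoRNAs, which guide pseudouridylation, were at a median of 0.12, vault RNAs at 0.33 (0.096 without siBMPR2 1), Y RNAs at -0.002 with a mean of 0.041, and 7SL and 7SK RNAs at 0.018, and these 4 lists did not pass. Over all features or adjusted over the list alone, 0 members of the 6 lists passed. The C/D box call ended without siControl 1 (adjusted p = 0.596; median 0.053, 110 higher and 90 lower) and without siBMPR2 2 (0.646; median 0.018, 105 higher and 94 lower). Its median was 0.064 without siBMPR2 3, 0.35 without siBMPR2 1 and 0.13 with library totals. That of the U RNAs ended without siControl 1 (0.596, median -0.29), siControl 2 (0.096, median -0.061), siBMPR2 2 (0.336, median 0.024) and siBMPR2 3 (0.341, median -0.25); the median was 0.65 without siControl 3, 0.15 without siBMPR2 1 and 0.20 with the block. H/ACA box snoRNAs passed without siControl 2 (0.00746), siControl 3 (3.61e-05) or siBMPR2 1 (3.87e-05), and Y RNAs without siControl 2 (0.00746) or siBMPR2 1 (0.012). With an estimated correlation these calls were lost, at adjusted p = 0.702, 0.569 and 0.525 for H/ACA box snoRNAs and adjusted p = 0.702 and 0.525 for Y RNAs.

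Across all small RNA features, 23 of 2015 passed the test, and all 23 were lncRNA intervals found almost only in vesicles of 1 group. In siBMPR2 vesicles 11 rose and 12 fell. Of those that rose, lnc-KLHL29-8 (chromosome 2, 22231099 to 22335509, GRCh38) had 505, 196 and 191 reads in siBMPR2 replicates 1 to 3 and 3, 2 and 2 in siControl, a log2 fold change of 7.19 ± 0.87 SE (edgeR adjusted p = 0.00816). lnc-DBX2-1 (chromosome 12, 45476752 to 45481348) rose by 8.30 ± 1.17 (adjusted p = 0.0173), and LINC01622, LINC02687 and ENSG00000257433.6 by 8.01 ± 1.33, 8.20 ± 1.37 and 7.44 ± 1.28. Of those that fell, AC040168.1 (chromosome 16, 56169679 to 56190007) had 1055, 53 and 181 reads in siControl replicates 1 to 3 and 1 read in each siBMPR2 library, a ratio of 403 (95% exact counting interval 138 to 1960, from reads pooled over libraries). lnc-TMEM132B-12 had 160 reads against 3, a ratio of 50 (16.8 to 245). Both intervals cover counting error only, not the spread between libraries. lnc-DKK1-5, lnc-KCNIP4-3 and LINC01720 had log2 fold changes of -7.27 ± 1.29, -6.54 ± 1.16 and -6.94 ± 1.29. All 10 named intervals moved the same way in 3 of 3 pairs, with adjusted p from 0.00816 to 0.0297. Since p chose them from the same libraries, the shared direction is no separate support.

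The reads of these intervals lay on few bases. In the library of most reads, the 11 intervals that rose covered a median of 21 bases (20 to 46) and the 12 that fell 30.5 bases (20 to 227), although the intervals reach 695762 bases. MALAT1, a nuclear lncRNA named here after its values were seen, covered 4953 bases with 458 reads. Reads of the other group came to 0.584% and 0.831% of those of the own group, and replicate 1 held 81.6% and 81.3% of the reads. Raw reads of the own group ranked replicate 1, then 3, then 2 in 10 of the 11 that rose and 11 of the 12 that fell. The intervals of a group thus varied together and need not be separate findings. Limma-voom called 1 of the 23 intervals, a higher one, the filter of 10 CPM left 8 calls (4 higher, 4 lower), and no filter gave 135 (28 higher, 107 lower). Without siControl 1 there were 0 calls, and without siControl 2 there were 38 (5 higher, 33 lower), of which 17 were among the 23. Without siBMPR2 2 there were 20, all higher, of which 11 were among the 23, so that all 12 calls of lower intervals ended. Without siBMPR2 1 or siBMPR2 3 there were 2, lnc-KLHL29-8 and lnc-DBX2-1. The fitted log2 fold changes of the named intervals that rose went down to between 5.57 and 6.60 without siBMPR2 1, and those of the named ones that fell shrank to between -6.80 and -4.56 without siControl 1.

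**Figure D4:**
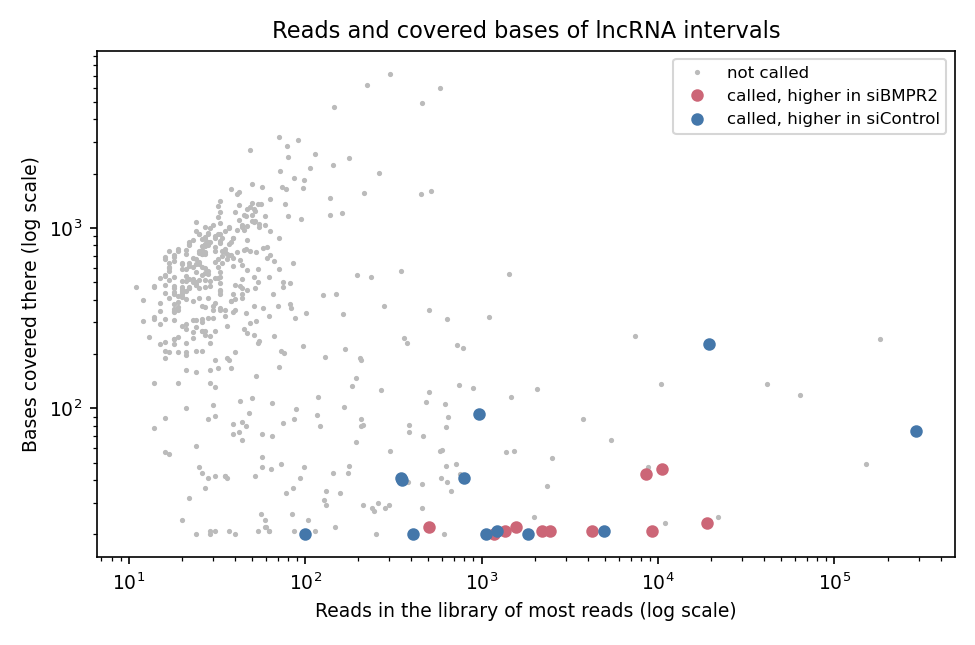
Reads in the library of most reads (horizontal axis, log scale) and bases covered there (vertical axis, log scale) for the 518 tested lncRNA intervals. Coloured points are the 23 intervals that passed the test, by the group in which they were higher, and grey points are the other 495. The 11 intervals higher in siBMPR2 covered 20 to 46 bases.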

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

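Of the alternatives in this part, those without the flat loci, without loci that share bases, with GC correction and without the called lncRNA intervals were chosen after the data were seen. The count of 0 called miRNAs was the same under all 20 alternatives. With the replicate number as a block, 0 miRNAs, 27 features and 4 lists were called, and the block ended no call of a named gene or list. Adjusted over the list alone, 5 members of the hypoxia list, 2 of the miR-29 family, 2 neural, 1 endothelial and 1 leukocyte and platelet miRNA passed with the block, and 2 of the hypoxia list and 2 neural without siControl 1. With the block and GC correction together these were 2 of the hypoxia list, 3 of the miR-29 family and 1 of leukocytes and platelets. All these counts are of loci, and near-identical copies among them cannot be separated. The alternatives planned for normalized values were not run, since the tables hold counts. The cause was not tested for the changes below unless the setting itself gives it. Leaving out a library kept its partner of the same number, so such changes mix the loss of a library with a broken pair.

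The 23 called features became 135 with no low-count filter, where 21639 features were tested, 8 with the stricter filter, where 966 were, and 1 with limma-voom; leaving out 1 library gave 0 to 38. The 4 called lists became 0 with an estimated correlation and 0 by fry; leaving out 1 library gave 0 to 6. No class share parted the groups, against 1 class without the called lncRNA intervals and 0 to 3 classes with 1 library left out (1 without siControl 1 or siControl 3, 2 without siControl 2, 3 without siBMPR2 1).

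Scaling turned small values. With library sizes over all features MIRLET7I was -0.008, MIR30C2 -0.03, MIR1-2 -0.01 and MIR143 -0.014. With library totals MIR26A2 was 0, MIR26A1 0.001 and MIR146B 0.021, and the medians of the senescence and inflammation list, the 7SL and 7SK list and the U RNAs were 0.06, -0.042 and -0.031. With the block the medians of the BMP and TGF-beta, DLK1-DIO3, senescence and inflammation, and Y RNA lists were 0, 0.002, 0.044 and 0.075. Without flat loci, the BMP and TGF-beta median was -0.144 and that of muscle and fibroblasts -0.158. Without the 10 largest features the tRNA difference was 0.967 points.

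Leaving out 1 library turned the sign of these values, none of which passed the test as single miRNAs, given as lowest and highest log2 fold change: MIR21 -0.424 and 0.21, MIR100 -0.686 and 1.124, MIRLET7G -0.334 and 0.147, MIR26A2 -0.218 and 0.131, MIR26A1 -0.216 and 0.105, MIR27A -0.677 and 0.279, MIR29A -0.509 and 0.156, MIR302B -0.132 and 0.571, MIR302C -0.116 and 0.571, MIR30C2 -0.035 and 0.205, MIR381 -0.354 and 0.544, MIR370 -0.479 and 1.059, MIR409 -0.365 and 0.87, MIR146A -0.753 and 0.324. For MIR222 they were -0.005 and 0.81, MIR1-1 -0.108 and 0.46, MIR1-2 -0.145 and 0.451, MIR143 -0.155 and 0.422, MIR199A1 -0.907 and 0.081, MIR451A -0.177 and 1.304, MIR363 -0.031 and 0.672, MIR342 -0.433 and 0.825, MIR146B -0.296 and 0.236, MIR200C -0.054 and 0.513, MIR200B -0.271 and 0.079, MIR200A -0.015 and 0.338, MIR192 -0.366 and 0.611, MIR194-2 -0.249 and 0.703, MIR137 -0.495 and 0.388.

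Other named miRNAs, none of which passed over all loci, kept their sign but moved by over 1.5 times with 1 library left out: MIR3615 0.933 to 2.168, MIRLET7I 0.038 to 0.222, MIR99A 0.382 to 0.854, MIR30A -0.643 to -0.117, MIR25 0.154 to 0.488, MIR27B -0.657 to -0.065, MIR221 0.043 to 0.709, MIR93 -1.196 to -0.494, MIR29C -0.717 to -0.382, MIR29B2 -0.902 to -0.462, MIR29B1 -0.885 to -0.412, MIR24-2 -0.554 to -0.253, MIR155 0.094 to 0.556, MIR122 0.486 to 1.586, MIR128-1 0.303 to 1.023 and MIR128-2 0.382 to 1.107. The same held for MIR127 (0.032 to 1.112), MIR30E (-0.594 to -0.006), MIR486 (0.183 to 0.793), MIR205 (0.12 to 0.725) and MIR24-1 (-0.584 to -0.295). It held too for MIRLET7F1 (-0.576 to -0.139), MIRLET7F2 (-0.577 to -0.168), MIR92A1 (0.199 to 0.688) and MIR92A2 (0.225 to 0.668).

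Fitted log2 fold changes of the named lncRNA intervals ranged, with 1 library left out, from 6.24 to 7.60 for lnc-KLHL29-8, 6.60 to 8.81 for lnc-DBX2-1, 6.22 to 8.55 for LINC01622, 6.33 to 8.74 for LINC02687, 5.567 to 7.995 for ENSG00000257433.6, -9.38 to -6.80 for AC040168.1, -6.07 to -4.56 for lnc-TMEM132B-12, -7.78 to -5.37 for lnc-DKK1-5, -7.04 to -4.59 for lnc-KCNIP4-3 and -7.50 to -5.05 for LINC01720.

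List medians ranged, with 1 library left out, from -0.397 to 0.043 for hypoxia, -0.282 to -0.092 for angiogenesis, -0.778 to -0.397 for miR-29, -0.531 to -0.129 for the miR-23, miR-27 and miR-24 clusters, -0.288 to 0.114 for BMP and TGF-beta, -0.278 to 0.15 for let-7, -0.155 to 0.062 for miR-30, -0.481 to 0.532 for DLK1-DIO3, -0.171 to 0.197 for senescence and inflammation, -0.219 to 0.183 for endothelium, -0.118 to 0.433 for muscle and fibroblasts, -0.029 to 0.242 for leukocytes and platelets, -0.365 to -0.104 for pulmonary hypertension, -0.132 to -0.001 for miRNAs that target BMPR2, -0.236 to -0.116 for the miR-17-92 paralogs, 0.048 to 0.513 for epithelium, 0.109 to 0.58 for liver and serum, and 0.278 to 0.542 for neural cells. Those of other RNA classes ranged from -0.21 to 0.274 for Y RNA, 0.018 to 0.35 for C/D box snoRNAs, 0.096 to 0.507 for vault RNA, -0.175 to 0.346 for H/ACA box snoRNAs, -0.153 to 0.21 for 7SL and 7SK and -0.291 to 0.652 for U RNAs. Differences of class shares ranged from -5.90 to 4.22 points for tRNA, -5.32 to 0.342 for miRNA, -8.25 to 2.79 for rRNA, -1.12 to 6.66 for snoRNA, -0.142 to 0.0727 for snRNA -0.00721 to 0.00445 for 7SL, -3.59 to -1.69 for lncRNA and 0.0128 to 0.0401 for RNase P and MRP RNA.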

Other observations

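Of the tests in this part, the correction for GC content was chosen before its result was seen; the tests of covered bases, of raw counts against depth, of serum miRNAs, of flat loci and of other splits were chosen after the results they concern were seen.

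The imprinted DLK1-DIO3 miRNAs of chromosome 14 set replicate 2 apart in both groups. The 26 tested members summed to 482 CPM in siControl 2 and 666 CPM in siBMPR2 2, against 2608 to 3811 CPM in the other 4 libraries. In each group, replicate 2 was the lowest library for 26 of 26 members. Leaving out siControl 2 or siBMPR2 2 alone thus kept such a low library in the other group only.

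A group of 12 miRNA loci had near-equal raw counts in all 6 libraries although miRNA totals ranged from 730890 to 2649607. MIR302B, of the pluripotency cluster, had 7131 to 9197 reads, MIR1-1, of striated muscle, had 2433 to 2952, and the others were MIR302A, MIR302C, MIR302D, MIR1-2, MIR143, MIR145, MIR148A, MIR182, MIR345 and MIR363; MIR302A, MIR302D, MIR145, MIR148A, MIR182 and MIR345 are named after their values were seen. MIR122, MIR451A and MIR486, abundant in serum, reached at most 0.504% of MIR302B, which argues against serum as the source of MIR302B. The comparison was with MIR302B alone, the most abundant of the 12. It does not decide for flat loci of low count, since MIR122 had 6 to 79 reads per library and MIR145 47 to 67. Of 6 further loci of pluripotent or muscle cells picked by name (6 to 72 reads each), the median slope of log2 count on log2 miRNA total was 0.144, against 0.811 for the 291 other tested loci outside both sets, so reads assigned from other libraries sequenced together may be a source. That slope stood at percentile 15.5 of other loci, which leaves release by the cells open, and so is any other source that adds a like number of reads to each library.

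The lncRNA intervals called between groups raise a hypothesis on short RNA. For the 11 higher in siBMPR2, the median of 21 covered bases is the length of a short RNA such as the transfected siRNA, which may be their source; transcription of the long genes is argued against by a median percentile of 0.0 for covered bases among uncalled intervals of like read count, although only 5 of the 11 had at least 10 such intervals. For the 12 higher in siControl the medians were 30.5 bases and percentile 11.7, which decide for neither; 8 of the 12 had at least 10 like intervals, among them lnc-KCNIP4-3 at percentile 48.1 of 27, while LINC02331 and lnc-EGLN3-1, named after their values were seen, had 2 and 3, too few for a percentile. No siRNA sequence was compared here, and a short RNA made by the cells from these places stays open too. The real split of the 6 libraries gave 23 calls and the highest of the other 9 splits 0; 10 splits are too few for a share under 0.05, and in the fit with the block the values were 27 and 0 over the 4 splits that part all pairs.

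The 4 miRNA lists that ranked lower in siBMPR2 were weighed against sequence composition. GC content correlated with the fold across loci (Spearman's rho 0.265, across loci, which are not independent), with -0.055, 0.315 and 0.206 in the 3 pairs. After correction for GC content 4 of the 4 calls remained, which argues against it as the whole cause; they also remained (4 of 4) without the loci of flat raw count, which decides nothing, since 0 members of these lists were flat. An effect of BMPR2 silencing stays open as untested, since no call held with an estimated correlation. The real split of the libraries gave 4 lists. The other splits gave 2, 1, 0, 2, 2, 3, 0, 3 and 2, so most of them called lists too. The highest of these was 3, and the splits are too few for a share under 0.05.

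For single miRNAs the count over splits says nothing: with a real count of 0, 10 of 10 splits had to give at least as many, and the highest other was 0. In the fit with the block, the real split called 0 miRNAs and 1 of the other splits that part all pairs called 5.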
